A study of Mus musculus with 4 samples.

How the data were processed

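Gene expression was measured with 4 two-colour Agilent mouse oligonucleotide arrays, each carrying 43379 non-control spots of 41174 probes. Per the labels, every array paired RNA of fetal liver erythroid precursors infected with a Hipk1 or Hipk2 short hairpin RNA (shRNA) in Cy3 with RNA of cells infected with a luciferase shRNA in Cy5. There were 2 arrays per target and no array with the dyes exchanged, so a dye effect cannot be separated from the knockdown. Each target had its own slide and its own scan, so slide or scan and target cannot be told apart. The starting material was 500 ng of RNA per channel.

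Per the file headers, the spot signals are raw intensity values, given as the mean pixel intensity of a spot and the median intensity of its local background in each dye, extracted with Agilent Feature Extraction 10.1.1.1. Those files also hold processed intensity values, which the scanner software had background-subtracted and dye-normalised, per the file headers. The deposited log ratio of each spot is a log10 ratio of processed Cy5 over Cy3, and the median deviation from that ratio was 4.75e-08. The authors also gave a table of log2 ratios, whose processing notes name limma without stating the version, the background correction or the normalisation. Comparison with the scanner files showed these deposited log2 ratios to be Cy5 over Cy3, with slopes of 0.995 to 1.01 against the best matching array, and they were turned to Cy3 over Cy5 here. The table's entries follow the spots in column-then-row order, as the correlations with the scanner files showed.

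The scanner files were read with R 4.3.3 and limma 3.58.1. Background was corrected with normexp and an offset of 50, and the log2 Cy3 over Cy5 ratios were normalised within each array by loess, with nothing further between arrays. Spots of one probe were averaged. Probes were kept when they were well above background in the same channel on both arrays of at least one target, and the probe of highest mean intensity stood for its gene. This left 24165 genes or other features, 16255 of them with a symbol. Symbols came from RefSeq accessions for 24913 of the 27544 spots that had one, and from the array files otherwise. Probe coordinates are those in the array files, on mouse genome build mm7. Exon and untranslated region assignments were not analysed here.

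The fit planned before the data were examined held the 4 arrays as labelled. Before any test, the spread between arrays was set against the spread between spots of one probe. The arrays labelled Hipk2 replicates 1 and 2 differed by little more than spots of one probe on one array, so they were averaged and counted as 1 sample, a choice made after the data were examined. The fit therefore held 3 samples, namely Hipk1 replicate 1, Hipk1 replicate 2 and the Hipk2 mean. It left 1 residual degree of freedom and a prior of 2.37, and the lone Hipk2 sample was assumed to vary like the Hipk1 arrays. The Hipk1 arrays differed mainly in Cy5, so their spread may not be that of 2 independent pairs of RNA. The planned fit to the 4 arrays is given beside it. Group means were fitted with lmFit and eBayes in limma. Hipk1 knockdown was compared with control, Hipk2 knockdown with control, and Hipk2 with Hipk1 knockdown as the test of the difference itself. Tests were two-sided, with a Benjamini-Hochberg adjusted p threshold of 0.05 over all genes. Where it is given, "adjusted over the list alone" means the same correction over one list's genes only.

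Gene lists, 27 in all and written before the data were examined, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over all lists. The gene lists covered globin, heme synthesis and mitochondrial iron, iron uptake and storage, red cell membrane and skeleton, erythroid transcription factors, early progenitor, late erythroid maturation, antioxidant, G1 to S phase, G2 and mitosis, CDK inhibitors, p53 targets, cell death regulators, EPO and STAT5 targets, HIPK kinases and partners, ER stress and amino acid response, ribosome biogenesis, heat shock, immediate early, and interferon response genes. The cell type lists covered macrophage, hepatocyte, megakaryocyte, mast cell and basophil, granulocyte, lymphoid, and endothelial and stromal markers. Camera with an estimated correlation and fry, a rotation test of whether a list's genes move on balance one way, were also run. Each list's median was placed among 10000 random lists of the same size matched on mean intensity.

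Genes named in the text were chosen by a rule fixed before the data were examined. It took Hipk1, Hipk2 and Hipk3, then the 6 genes highest and the 6 lowest among those passing the threshold. Where fewer passed, it took those with the smallest p whose arrays of a target went the same way, passing over clone and accession names. It then took the members with the smallest p from each called list, and the 1 with the smallest p from each other list where that p was under 0.05. Some members of lists were left out of the text beyond 30 genes per comparison. Genes named outside the rule are given as chosen after their values were seen.

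The fit was tested on simulated data, with 200 changed genes and the spread of the Hipk1 arrays. That spread came from the single difference of each gene, which scatters more between genes than true spreads do. At that spread the fit recovered 0 of the 200 in each comparison at log2 changes of 1, 2 and 3, with 0 false calls. As nothing was called, these 0 false calls say nothing of error control. At 0.25 times that spread the fit recovered 148 of 200 for Hipk1, 119 for Hipk2 and 115 for the difference, with 0 false calls. Of 100 simulated lists without a shift, 2 had a camera p under 0.05, and all 100 lists shifted by 0.5 did. The genes of these lists were drawn independently, so this gives no error rate for lists whose genes move together.

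The alternatives were no background correction, plain subtraction, Agilent's processed signals, median centring in place of loess, Aquantile between arrays, no filter and a stricter filter on dim probes, the mean of a gene's probes, the Hipk1 arrays alone, an intensity trend with a robust prior, array weights, the replicate number as a block, the authors' value table, other thresholds, and leaving out each array in turn. The replicate block was run on the 4 arrays as labelled. The planned fit of these arrays became an alternative, and the value table less 1 of its Hipk1 columns was added as one, after the data were examined.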

Results

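Expression was measured in erythroid precursors of C57Bl6 mouse fetal liver at stage E14.5, selected for lack of TER119, a surface marker of maturing red cells. The cells were infected with retroviruses carrying an shRNA against Hipk1, Hipk2 or luciferase, and were harvested after 36 hours of differentiation. Hipk1 and Hipk2 are nuclear serine/threonine kinases that act with transcriptional corepressors. Per the labels, each of the 4 arrays set a knockdown (Cy3) against the luciferase control (Cy5), with 2 arrays for Hipk1 and 2 for Hipk2. The probes of the targets did not show a lower signal in Cy3 throughout, so knockdown and control stand here for channels as labelled. The share of spots well above background was 71.0% and 73.7% in Cy3 on Hipk1 replicates 1 and 2, and 76.4% and 76.5% on Hipk2 replicates 1 and 2. In Cy5 it was 76.1% and 75.8% for Hipk1, and 82.2% and 80.7% for Hipk2. The number of arrays limits the precision of every value. Ratios are given as log2 Cy3 over Cy5, so a negative value means a higher signal in Cy5, the channel labelled control.

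The arrays of a target were alike to different degrees. Over 11583 bright spots, log2 ratios differed between the Hipk1 arrays with a robust SD of 0.392, and between the Hipk2 arrays with a robust SD of 0.0703. In bands of intensity, the spread between the Hipk2 arrays was 1.08 to 1.30 times that between spots of one probe, against 2.38 to 9.25 times for the Hipk1 arrays. The Hipk2 arrays were therefore counted as 1 sample. On the Hipk1 slide the Cy3 signals differed with a robust SD of 0.0577 and the Cy5 signals with 0.409, so the channel labelled knockdown was the one in which the 2 arrays were alike. Between the Hipk2 arrays the robust SDs were 0.0951 in Cy3 and 0.107 in Cy5. The Hipk1 arrays were thus at least as alike in Cy3. The spread of their ratios, and each SE taken from it, reflects mostly Cy5, and they may not be 2 independent pairs of RNA. Across slides, both channels differed with robust SDs of 0.345 to 0.602.

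The probes of the targeted kinases asked whether each transcript was lower in the channel labelled knockdown. Hipk2 was higher in that channel at its brightest probe, A_51_P125316 (chromosome 6, 38618549 to 38618608, build mm7). This probe gave 1.66 and 1.77 on the 2 Hipk2 arrays, or 3.16-fold and 3.41-fold higher in Cy3. On the Hipk1 arrays it gave 0.33 on replicate 1 and 1.88, or 3.69-fold, on replicate 2. The other Hipk2 probes were nearer 0 on the Hipk2 arrays and Hipk1 replicate 2, but not all on Hipk1 replicate 1. They gave 0.58, 0.69, 0.64 and 0.60 at A_51_P318292, and 0.14, 0.48, 0.10 and 0.20 at A_52_P554845, for Hipk1 replicates 1 and 2 and then Hipk2 replicates 1 and 2. In the same order, A_52_P29583 gave 0.33, -0.64, 0.27 and 0.24.

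Hipk1 differed between the arrays labelled with its knockdown. At its brightest probe, A_52_P268687 (chromosome 3, 103534209 to 103534268, build mm7), the ratios were 0.42 on Hipk1 replicate 1 and -0.26 on Hipk1 replicate 2, with -0.43 and -0.38 on the Hipk2 arrays. A_51_P147878 gave 1.08 and 0.09 on the Hipk1 arrays and 0.46 and 0.43 on the Hipk2 arrays. A_52_P235929 gave 0.71 and 0.14, and then -0.20 and -0.33. In limma the Hipk1 mean of the brightest probe was 0.08 ± 0.21 (SE, n = 2 arrays), adjusted p = 0.911, with 0.36 as the mean of its probes, and under median centring its sign turned to -0.34. For Hipk2 in the Hipk2 comparison the effect was 1.71 ± 0.61 (SE taken from the Hipk1 arrays), adjusted p = 1, and adjusted p = 0.114 with the 4 arrays counted as labelled. It was 0.68 as the mean of the Hipk2 probes and 1.04 under median centring. Hipk3, a related kinase, was at -0.03 ± 0.14 in the Hipk1 comparison and 0.33 ± 0.20 in the Hipk2 comparison.

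**Figure D1:**
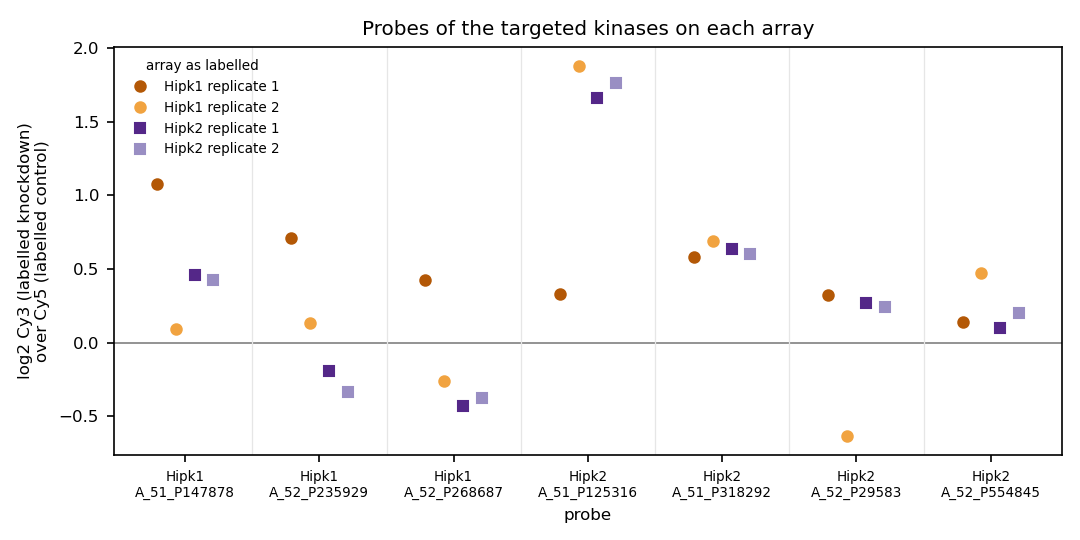
Log2 Cy3 (labelled knockdown) over Cy5 (labelled control) of each Hipk1 and Hipk2 probe, 1 point per array. The brightest Hipk2 probe, A_51_P125316, lies at 1.66 and 1.77 on the Hipk2 arrays, at 1.88 on Hipk1 replicate 2 and at 0.33 on Hipk1 replicate 1.

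The authors' table of log2 ratios was matched to the arrays across genes, which are not independent replicates. The column labelled Hipk1 replicate 1 had r = 0.963 with the array labelled Hipk1 replicate 2, and the column labelled Hipk1 replicate 2 had r = 0.991 with the array labelled Hipk1 replicate 1. The Hipk2 columns had r of 0.741 to 0.823 with the Hipk2 arrays and r = 0.847 with each other, with a robust SD of 0.168. Values from the table are named as such wherever they are given.

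**Figure D2:**
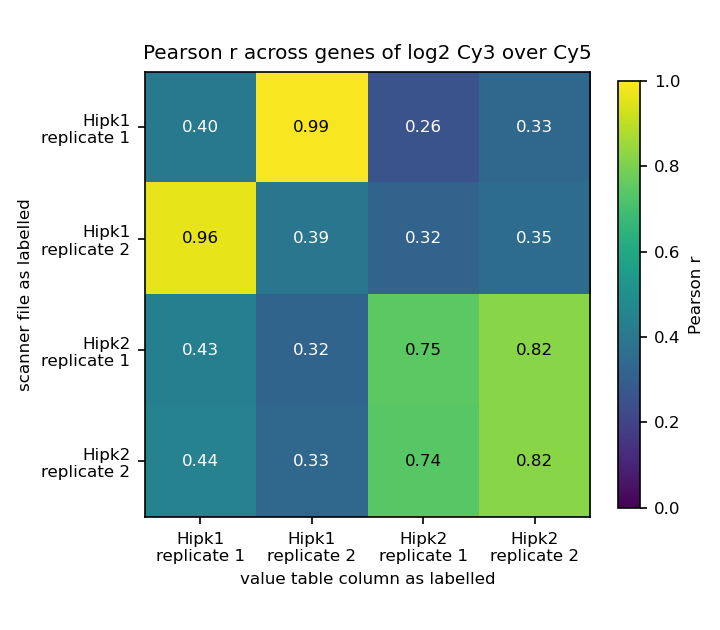
Pearson r across genes of log2 Cy3 over Cy5, with the arrays in the vertical direction and the columns of the authors' value table in the horizontal direction, as labelled. The Hipk1 columns match the Hipk1 arrays crosswise (0.963 and 0.991), and the Hipk2 columns reach at most 0.823 with a Hipk2 array.

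The comparison labelled Hipk1 knockdown against control addressed which transcripts differ between the channels of the 2 Hipk1 arrays. Hipk1 itself was not lower in Cy3 on both, so directions are given by dye. Interferon response genes were the group furthest from 0, with higher signal in Cy5 on both arrays. Isg15, an interferon-induced ubiquitin-like protein, had a log2 ratio of -2.92 ± 0.24 (SE, n = 2 arrays), which is 7.56-fold higher in Cy5. Usp18, the protease that removes it from proteins, had -2.95 ± 0.33, or 7.73-fold. Genes of late erythroid maturation leaned to Cy3, led by the nuclear exporter Xpo7 at 1.49 ± 0.14, or 2.81-fold higher in Cy3, though the median of that list turned negative under median centring, at percentiles 100 and 99.99 of intensity-matched lists.

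Among single genes, Irf9, the DNA-binding part of the interferon-activated transcription complex, was at -1.70 ± 0.11, with -1.81 and -1.60 on the 2 arrays. Egln3, a prolyl hydroxylase that marks hypoxia-inducible factors for degradation, was at -1.45 ± 0.09. The glycolytic enzymes Aldoa and Pgk1 were at -1.36 ± 0.10 and -1.35 ± 0.10, and Slc16a3, a lactate exporter, was at -1.18 ± 0.10. On the Cy3 side, Ackr3, a scavenging receptor for chemokines, was at 1.11 ± 0.09, and the secreted glycoprotein Reln was at 1.09 ± 0.11. The small GTPase Arl4a was at 1.13 ± 0.11, the membrane protein Ldlrad4 at 1.17 ± 0.13, and the calcium-dependent kinase Dapk2 at 0.98 ± 0.11. No gene passed: limma gave 0 of 24165, with a smallest adjusted p of 0.597, and 1936 genes at an unadjusted p under 0.05 where 1208 would fall by chance. The 4 arrays as labelled also gave 0 (5146 unadjusted), and the authors' value table gave 0 (4340 unadjusted). At least 2-fold on both arrays were 8 genes higher in Cy3 and 45 higher in Cy5, with 285 and 619 on replicate 1 but 13 and 54 on replicate 2.

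Camera called 11 of the 27 lists in the Hipk1 comparison, 8 towards Cy3 and 3 towards Cy5. With an estimated correlation none of the calls held in any of the 3 comparisons, but that test had little power at 1 residual degree of freedom. The p-values at the preset correlation of 0.01 may in turn be too small for lists whose genes move together. The estimated correlation was 1 for the interferon list. Under median centring camera at the preset correlation called 6, with 0 towards Cy3 and 6 towards Cy5. The interferon list had a median of -1.41 (adjusted p = 6.42e-17, and adjusted p = 0.863 with an estimated correlation), with medians of -2.00 and -0.72 on replicates 1 and 2. Of its 30 measured genes, 28 were higher in Cy5 on all 4 arrays, 0 passed over all genes and 15 passed when adjusted over the list alone. The median of the late erythroid maturation list was 0.40 (adjusted p = 9.8e-10, and 0.863 as adjusted p with an estimated correlation), and 18 of its 27 genes were higher in Cy3 on both arrays. Of these genes 0 passed over all genes and 2 when adjusted over the list alone. Ube2o, a ubiquitin ligase that clears proteins from reticulocytes, was at 1.23 ± 0.17, and Bpgm, which makes the bisphosphoglycerate that loosens oxygen from hemoglobin, was at 0.89 ± 0.14. In the other 9 called lists 0 genes passed over all genes and 0 when adjusted over the list alone.

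Other erythroid lists leaned the same way. The red cell membrane and skeleton list had a median of 0.51 (adjusted p = 3.72e-08), heme synthesis and mitochondrial iron 0.40 (adjusted p = 7.14e-06), erythroid transcription factors 0.30 (adjusted p = 0.00882) and globin 0.26 (adjusted p = 0.0079). Each of these 4 had adjusted p = 0.863 with an estimated correlation. All 4 medians, and that of late erythroid maturation, turned negative under median centring, to between -0.23 and -0.02, where a trend with intensity remains. Among intensity-matched lists they then lay, on replicates 1 and 2, at percentiles 100 and 99.99 for late maturation, 100 and 95.7 for membrane, 100 and 84.2 for heme, 99.97 and 83.4 for transcription factors and 98.4 and 14.4 for globin. They rested mostly on replicate 1, with medians of 0.85 for membrane, 0.81 for heme, 0.54 for transcription factors, 0.65 for globin and 0.75 for late maturation there, against 0.18, 0.01, 0.09, 0.03 and 0.11 on replicate 2. On replicate 1 the macrophage list was at -0.72, early progenitor at -0.50, megakaryocyte at -0.44 and granulocyte at -0.33. Named members were the skeletal proteins Epb41 (1.21 ± 0.24) and Add2 (0.71 ± 0.16), the mitochondrial iron importer Slc25a37 (0.88 ± 0.18) and the heme enzyme Alad (0.56 ± 0.16, but -0.09 under median centring). The embryonic globins Hbb-bh1 and Hba-x were at 0.92 ± 0.18 and 0.28 ± 0.09, the hematopoietic cofactor Lmo2 at 0.81 ± 0.19 and Mllt3, a reader of acylated histones, at 0.61 ± 0.15. With a Hipk1 array left out, Alad ranged from 0.31 to 0.80 and Lmo2 from 0.51 to 1.12.

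Outside the erythroid lists, G2 and mitosis had a median of 0.18 (adjusted p = 1.47e-06), ER stress and amino acid response 0.14 (adjusted p = 0.0079) and immediate early genes 0.16 (adjusted p = 0.0189), all 3 with adjusted p = 0.863 with an estimated correlation and all 3 negative under median centring, at -0.28, -0.35 and -0.02. Among intensity-matched lists they then lay at percentiles 99.4 and 57.6, 90.3 and 84.6, and 99.9 and 99.7 on replicates 1 and 2. Their medians on replicates 1 and 2 were 0.33 and 0.02, 0.28 and 0.09, and 0.33 and 0.06. The ER stress call was also lost with Agilent's processed signals. Prc1, which bundles spindle microtubules for cytokinesis, was at 0.69 ± 0.09 and the phosphatase Cdc25c at 0.52 ± 0.10. Xbp1, a transcription factor of the unfolded protein response, was at 0.45 ± 0.09, and Ppp1r15a, which restores translation after stress, at 1.00 ± 0.23. The rapidly induced genes Ier2 and Klf6 were at 0.89 ± 0.13 and 0.72 ± 0.11. Ribosome biogenesis leaned to Cy5 with a median of -0.25 (adjusted p = 0.005, and adjusted p = 0.863 with an estimated correlation), at -0.46 on replicate 1 and -0.04 on replicate 2, and -0.71 under median centring. Among intensity-matched lists it then lay at percentiles 0 and 52.2 on replicates 1 and 2, so the lean rested on replicate 1. Its nucleolar members Npm1 and Gnl3 were at -0.59 ± 0.18 and -0.40 ± 0.11. With a Hipk1 array left out, Npm1 ranged from -0.88 to -0.31 and Ppp1r15a from 0.62 to 1.38.

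Macrophage, granulocyte and early progenitor markers were lowest on Hipk1 replicate 1, while mast cell (-0.04 and 0.02) and lymphoid markers (0.0043 and 0.05) lay near 0 on both Hipk1 arrays. The macrophage list had a median of -0.34 (adjusted p = 0.00882, and adjusted p = 0.863 with an estimated correlation), which was -0.72 on replicate 1 and -0.01 on replicate 2. The call was lost under median centring (median -0.47, adjusted p = 0.751). The complement gene C1qc was at -0.45 ± 0.12, whereas Timd4, a receptor for dying cells, was at 0.42 ± 0.12, or 0.27 to 0.57 with a Hipk1 array left out. On replicate 1 alone, and chosen after their values were seen, the macrophage receptor Marco was at -3.61 and lysozyme (Lyz2) at -2.59, and the granule proteins Mpo and Ctsg were at -3.85 and -3.43. On replicate 2 these 4 genes were at -0.09, 0.40, 0.22 and 0.08. The granulocyte list (median -0.18, adjusted p = 0.42) and the early progenitor list (median -0.23, adjusted p = 0.251) were not called, with medians of -0.33 and -0.50 on replicate 1 against 0.11 and 0.03 on replicate 2. Megakaryocyte markers were at -0.44 on replicate 1 and 0.56 on replicate 2 (adjusted p = 0.445).

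**Figure D3:**
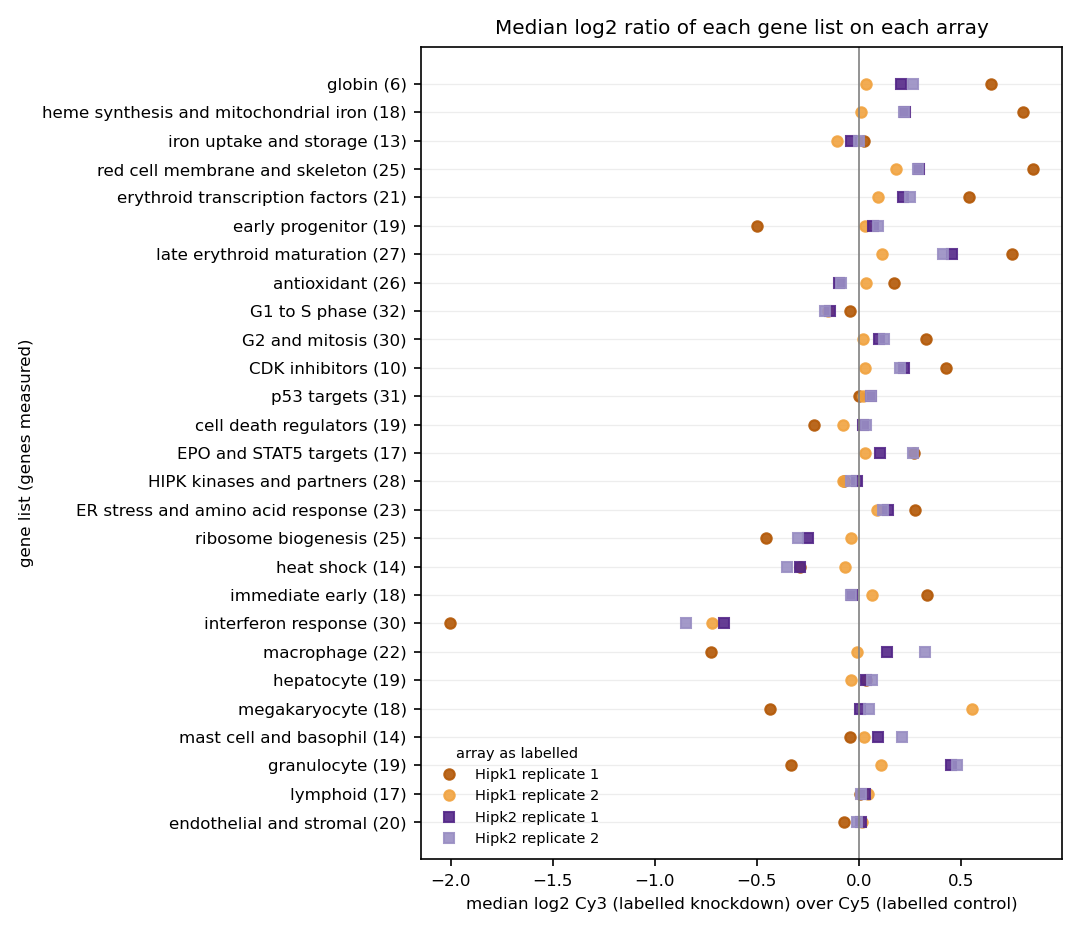
Median log2 Cy3 over Cy5 of each gene list, 1 point per array, with the number of genes measured in brackets. Interferon genes lie at -2.00, -0.72, -0.66 and -0.85 on the 4 arrays under loess and stay negative under median centring, while the positive medians of the erythroid lists, of G2 and mitosis, of ER stress and of CDK inhibitors turn negative under median centring on the arrays other than Hipk1 replicate 1, and for G2 and mitosis and ER stress on that array too.

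On Hipk1 replicates 1 and 2, megakaryocyte markers were at -0.44 and 0.56, and EPO and STAT5 targets at 0.27 and 0.03, which the mean of the arrays hides. Lists called in no comparison from the scanner files had medians near 0 for the Hipk1 mean, namely iron uptake and storage (-0.0071), p53 targets (-0.07), cell death regulators (-0.09), EPO and STAT5 targets (0.06), HIPK kinases and partners (-0.05), hepatocyte (-0.03), megakaryocyte (0.02), lymphoid (0.04), and endothelial and stromal (-0.03). For Hipk2 their medians were -0.03, 0.06, 0.04, 0.19, -0.05, 0.06, 0.02, 0.02 and 0.01 in the same order, and the smallest adjusted p among them was 0.109, for EPO and STAT5 targets. The value table called p53 targets for Hipk2 (median 0.17, adjusted p = 0.0368, and 0.918 as adjusted p with an estimated correlation).

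The comparison labelled Hipk2 knockdown against control addressed which transcripts differ between the channels of the 2 Hipk2 arrays. Hipk2 itself was higher in Cy3 on both, so directions are again given by dye. Named genes on the Cy3 side included Pitpna, a phosphatidylinositol carrier, at 2.00 ± 0.16 (SE taken from the Hipk1 arrays, n = 1 sample) and the ubiquitin ligase Rnf115 at 1.79 ± 0.13, or 3.46-fold. Rb1, the retinoblastoma protein that restrains entry into S phase, was at 1.77 ± 0.26, or 3.41-fold. Hbb-bh1 was at 1.51 ± 0.25, or 2.86-fold higher in Cy3. As in the Hipk1 comparison, interferon genes had higher signal in Cy5, with Isg15 at -1.70 ± 0.34 or 3.25-fold, but in the authors' value table Isg15 was at 0.26.

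Further genes on the Cy3 side were Mbnl1, a regulator of splicing, at 1.56 ± 0.13, Atp6v0e, a subunit of the vacuolar proton pump, at 1.53 ± 0.14, Tpd52l2 at 1.51 ± 0.14 and Frmd8 at 1.502 ± 0.13. On the Cy5 side were the kinesin light chain Klc1 at -1.54 ± 0.23, the growth inhibitor Osgin1 at -1.40 ± 0.20, the receptor Treml4 at -1.06 ± 0.14 and Wdr22 at -0.998 ± 0.13. The splicing factor Hnrnpa1 was at -0.98 ± 0.14 and the transcription factor subunit Gtf3c3 at -0.90 ± 0.13. Another probe of Mbnl1 gave the opposite sign on the Hipk2 arrays. The limma error came from the Hipk1 arrays, which differed with a robust SD of 0.392 against 0.0703 for the Hipk2 arrays. At that spread the fit recovered 0 of 200 simulated genes, with log2 changes of up to 3. A low count of genes in the main fit therefore does not show that there was no effect. Limma gave 0 genes, with a smallest adjusted p of 1 and 1077 genes at an unadjusted p under 0.05, fewer than the 1208 that chance gives. Counted as 4 arrays, as planned before the data were examined, the fit called 230 genes (145 higher in Cy3, 85 higher in Cy5), and the authors' value table called 2088 (822 and 1266). The fit to 4 arrays pools the spread of both targets and counts the 2 Hipk2 hybridisations as separate samples. These 2 differed by little more than spots of one probe. With the replicate number as a block the same 4 arrays gave 0 genes. At least 2-fold on both arrays were 107 genes in Cy3 and 29 in Cy5.

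Camera called 14 lists, 10 towards Cy3 and 4 towards Cy5, each with adjusted p = 0.768 with an estimated correlation. Median centring gave 12, with 3 towards Cy3 and 9 towards Cy5. The authors' value table gave 8, of which 6 were called in the same direction in both. In each called list 0 genes passed over all genes, and when adjusted over the list alone 1 passed in globin, 1 in CDK inhibitors and 0 in the other 12. The interferon list had a median of -0.75 (adjusted p = 1.47e-10), with -0.66 and -0.85 on the 2 arrays and 29 of 30 genes higher in Cy5 on both, but 0.15 in the value table (adjusted p = 0.456). Its member Irf9 was at -0.71 ± 0.16, and at 0.51 in the table.

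Erythroid lists again leaned to Cy3 under loess and turned negative under median centring. Late erythroid maturation had a median of 0.45 (adjusted p = 9.31e-09), red cell membrane and skeleton 0.28 (adjusted p = 0.0011), globin 0.27 (adjusted p = 0.0105), heme synthesis and mitochondrial iron 0.23 (adjusted p = 0.000647) and erythroid transcription factors 0.23 (adjusted p = 0.000677), against -0.14, -0.47, -0.61, -0.50 and -0.28 under median centring. Among intensity-matched lists they then lay at percentiles 100 and 100, 99.4 and 99.5, 68.3 and 89.3, 99.2 and 99.2, and 99.8 and 100 on the 2 arrays. Higher in Cy3 on both arrays were 23 of 27 late maturation genes, 20 of 25 membrane genes and all 6 globin genes. Xpo7 was at 1.19 ± 0.20, the Myc antagonist Mxi1 at 1.28 ± 0.30, Slc25a37 at 1.33 ± 0.25 and the heme enzyme Urod at 0.63 ± 0.22. Bcl11a, a repressor of globin genes, was at 0.93 ± 0.14, Mllt3 at 0.99 ± 0.21, the water channel Aqp1 at 0.68 ± 0.16 and the membrane scaffold Mpp1 at 0.81 ± 0.19. Urod and Mpp1 turned to -0.30 and -0.03 under median centring. In the value table the calls of globin (adjusted p = 0.116), heme synthesis (adjusted p = 0.14) and erythroid transcription factors (adjusted p = 0.0798) were lost, with medians of 0.17, 0.21 and 0.20.

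Cell cycle lists went both ways. G1 to S phase had a median of -0.14 (adjusted p = 0.00111), or -0.87 under median centring, with 25 of 32 genes higher in Cy5 on both arrays and Ccne2, the cyclin that drives entry into S phase, at -1.37 ± 0.31, or 2.59-fold higher in Cy5. CDK inhibitors had a median of 0.22 (adjusted p = 0.0237) and G2 and mitosis 0.11 (adjusted p = 0.00361), which were -0.11 and -0.53 under median centring. The second of these was called towards Cy5 under median centring (adjusted p = 0.00217), yet its medians there lay at percentiles 98.3 and 94.7 of intensity-matched lists on the 2 arrays, which is the Cy3 side. The centromere histone Cenpa was at 0.92 ± 0.14. Ribosome biogenesis had a median of -0.28 (adjusted p = 2.58e-05), or -0.89 under median centring, with 24 of 25 genes higher in Cy5 on both arrays, among them the nucleolar genes Nop16 (-0.52 ± 0.21) and Noc4l (-0.34 ± 0.14). Heat shock genes had -0.32 (adjusted p = 0.00361), or -0.96 under median centring, with the chaperone Hsp90aa1 at -0.72 ± 0.14. In the value table G1 to S phase was at -0.24 and ribosome biogenesis at -0.46, and the calls of CDK inhibitors (adjusted p = 0.161) and of G2 and mitosis (-0.0014, adjusted p = 0.518) were lost.

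Granulocyte, macrophage and mast cell markers leaned to Cy3 on both Hipk2 arrays, while lymphoid (adjusted p = 0.924) and megakaryocyte markers (adjusted p = 0.224) were not called. The granulocyte list had a median of 0.46 (adjusted p = 7.42e-08), but 0.045 under median centring, with 18 of 19 genes higher in Cy3 on both arrays and the granule genes Ngp and Camp at 0.92 ± 0.14 and 0.87 ± 0.13. Macrophage markers had 0.26 (adjusted p = 0.00814), or 0.028 under median centring (adjusted p = 0.0381), with C1qb at 0.28 ± 0.13, which turned to -0.10 under median centring. Mast cell and basophil markers had 0.13 (adjusted p = 0.00948), but 0.039 and no call under median centring (adjusted p = 0.122), with the basophil protease Mcpt8 at 0.42 ± 0.20. Under median centring the granulocyte, macrophage and mast cell lists lay at percentiles 100 and 99.99, 99.5 and 99.8, and 99.96 and 99.7 of intensity-matched lists on the 2 arrays. In the value table the granulocyte list was at 0.27 (adjusted p = 0.0254, and 0.918 as adjusted p with an estimated correlation), with Ngp at 0.40 and Camp at 0.27. Macrophage markers were at 0.04 there (adjusted p = 0.456), and the mast cell call was lost (0.17, adjusted p = 0.0521).

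The difference between the knockdowns was tested directly as Hipk2 minus Hipk1, in which a dye effect common to all arrays cancels. An effect of slide or scan does not cancel, as each target had its own. The lysosomal protease Ctsl was at 2.27 ± 0.27, with a mean of 1.59 on the Hipk2 arrays and -0.68 on the Hipk1 arrays. Markers of granulocytes and macrophages were higher in Hipk2 ratios, with median differences of 0.70 and 0.79, or 0.38 and 0.23 without Hipk1 replicate 1. Interferon genes were higher too, but their difference rested on Hipk1 replicate 1 in the scanner files and was larger in the value table. Osgin1 and Treml4 were below 0, at -1.55 ± 0.25 and -1.38 ± 0.17.

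Other genes above 0 were Pitpna at 1.84 ± 0.19, Tpd52l2 at 1.68 ± 0.18, the respiratory subunit Cox6a1 at 1.57 ± 0.18, the translation factor Eif4h at 1.55 ± 0.16 and Egln3 at 1.38 ± 0.16. Genes below 0 were Ier2 at -1.19 ± 0.22, Unkl at -1.12 ± 0.17, the steroid and fatty acid enzyme Hsd17b12 at -0.98 ± 0.18 and Myef2 at -0.89 ± 0.17. Another probe of Hsd17b12 gave the opposite sign on the arrays of both targets, as did other probes of Osgin1, Unkl and Il1rl1 on the Hipk1 arrays and of Txnrd2 on the Hipk2 arrays. No gene passed in limma, with a smallest adjusted p of 1 and 471 genes at an unadjusted p under 0.05 against 1208 by chance. The error of that fit came from the Hipk1 arrays here too, so the low count does not show that there was no difference. The 4 arrays as labelled also gave 0 (2783 unadjusted), and the value table gave 0 (3366 unadjusted).

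Camera called 8 lists, 5 above 0 and 3 below, each with adjusted p = 0.981 with an estimated correlation, and with 0 genes passing over all genes or adjusted over the list alone. Median centring gave 12, with 4 above 0 and 8 below. Granulocyte markers had a median difference of 0.70 (adjusted p = 1.15e-09), or 0.38 without Hipk1 replicate 1, and 18 of 19 had both Hipk2 arrays above both Hipk1 arrays. Camp was at 0.72 ± 0.16, Ngp at 0.71 ± 0.17 and Fcnb, a granulocyte lectin, at 0.65 ± 0.16. Macrophage markers had 0.79 (adjusted p = 8.56e-06), or 0.23 without Hipk1 replicate 1, and included C1qc at 0.77 ± 0.22, the pore protein Mpeg1 at 0.92 ± 0.46 and Adgre1, the F4/80 antigen, at 1.68 ± 0.87, of which the last 2 were at 0.47 and 0.77 without Hipk1 replicate 1. Mast cell and basophil markers had 0.09 (adjusted p = 0.0216), 0.06 without Hipk2 replicate 2 (adjusted p = 0.0528) and 0.16 without Hipk2 replicate 1. Il1rl1, the receptor of interleukin 33, was at 0.76 ± 0.27, Gzmb at 0.73 ± 0.27 and Hdc, which makes histamine, at 1.26 ± 0.62, or 0.635 without Hipk1 replicate 1. In the value table these 3 lists were at 0.38, 0.44 and 0.16 and called, but with an estimated correlation the calls were lost there too (adjusted p = 0.818, 0.884 and 0.818), and Camp and Ngp were at 0.11 and 0.15.

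Interferon genes had a median difference of 0.75 (adjusted p = 4.65e-05), which was -0.0015 without Hipk1 replicate 1 and 1.22 without Hipk1 replicate 2, and which lost its call with an intensity trend and a robust prior (adjusted p = 0.489). In the value table it was 1.68 (adjusted p = 8.91e-12, and adjusted p = 0.818 with an estimated correlation), with list medians of -0.83 and -2.12 in the Hipk1 columns and 0.33 and -0.15 in the Hipk2 columns. Isg15 was at 1.22 ± 0.41, Irf9 at 1.00 ± 0.19 and the antiviral enzyme Rsad2 at 2.53 ± 0.96 (1.54 without Hipk1 replicate 1), against 3.20, 2.22 and 4.84 in the table. Early progenitor genes had 0.21 (adjusted p = 0.0347), with 0.06 without Hipk1 replicate 1 and 0.48 without Hipk1 replicate 2, and lost the call with the 4 arrays as labelled (adjusted p = 0.0597) and in the value table (0.11, adjusted p = 0.321). The stem cell factor receptor Kit was at 1.28 ± 0.55 and Cd33 at 0.57 ± 0.28, or 0.72 and 0.33 without Hipk1 replicate 1. Antioxidant genes had -0.23 (adjusted p = 0.00626), or -0.11 without Hipk1 replicate 1 and -0.34 in the value table, with the thioredoxin inhibitor Txnip at -0.77 ± 0.16 and the mitochondrial thioredoxin reductase Txnrd2 at -0.86 ± 0.31, but the peroxiredoxin Prdx5 at 0.50 ± 0.19. Immediate early genes had -0.15 (adjusted p = 0.00968), but were not called in the value table (-0.05, adjusted p = 0.318), with Jun at -0.96 ± 0.34 and Klf2 at 0.46 ± 0.17. G1 to S phase had -0.09 (adjusted p = 0.0237), or -0.25 without Hipk1 replicate 2 and -0.17 in the value table, with Ccne2 at -1.37 ± 0.38 and Cdk6 at 1.95 ± 0.59. It lost the call with plain background subtraction (adjusted p = 0.102), with Agilent's processed signals, and with an intensity trend and a robust prior.

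Across 24165 genes, which are not independent replicates, the mean ratios of the 2 knockdowns correlated with r = 0.432 and rho = 0.388 (covariance 0.0294), against r = 0.395 between the Hipk1 arrays and r = 0.927 between the Hipk2 arrays. The dyes stood the same way and the control was a luciferase shRNA on all 4 arrays, so neither a dye effect nor a shared control can be separated from this correlation. It was 0.371 in the value table and 0.67 under median centring. At least 1.5-fold in the same direction on all 4 arrays were 48 genes in Cy3 and 53 in Cy5. Of these, 41 and 3 did so in the value table as well.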

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

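The tests of explanations given here were all chosen only after the result was seen, while the lists and the test of their difference, for 4 arrays, were written before the data were examined. The difference between the targets was called by camera, Hipk2 minus Hipk1, for 8 lists, all with adjusted p = 0.981 with an estimated correlation. The median differences were 0.70 for granulocyte markers, 0.79 for macrophage markers, 0.75 for interferon response genes, 0.21 for early progenitor genes and 0.091 for mast cell and basophil markers. They were -0.23 for antioxidant genes, -0.15 for immediate early genes and -0.086 for G1 to S phase genes. Without Hipk1 replicate 1 the medians were 0.38 for granulocyte, 0.23 for macrophage, -0.0015 for interferon and 0.06 for early progenitor genes.

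Interferon genes were higher in Cy5 on all 4 arrays for 28 of 30, and in the scanner files their difference between targets rested on Hipk1 replicate 1, whereas the value table gave a median difference of 1.68. A dye bias of the probes as the whole cause is argued against by the 2 arrays of the Hipk1 slide, which differed by a median of -1.12 over the list, with 30 of 30 genes lower on replicate 1. More RNA of macrophages in Cy5 may account for part of the value on Hipk1 replicate 1, where the macrophage list had a median of -0.723 and 20 of its 22 genes lay under 0, with Ctss at -2.66 and Lyz2 at -2.59 but C1qb at 0.25 and Timd4 at 0.57. Early progenitor (-0.50), megakaryocyte (-0.44) and granulocyte lists (-0.33) were also low on Hipk1 replicate 1, so the shift there was not particular to macrophages. Mast cell (-0.04) and lymphoid markers (0.0043) lay near 0 on it. On the other 3 arrays the macrophage median was 0.187, which argues against macrophage RNA as the source there. Selection for lack of TER119 would not remove macrophages, and the targets themselves and the shRNA in each channel stay open as untested explanations. Slide or scan cannot be told apart from the target in any of these differences.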

How the results depend on the processing

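Counting the Hipk2 arrays as 1 sample was chosen after the data were seen, so the planned fit of the 4 arrays as labelled, with or without the replicate block, stands here as an alternative. The value table less 1 column was also chosen only after the data were seen, and the other alternatives before. Of values whose test the setting could alter, 401 of called lists kept direction and call, 104 of counts and targets stayed within 1.5 times or kept direction, and 1148 of named genes kept direction. As 0 genes pass, the last speak only for direction, which the 4-array fits (same means) and dim-probe filters could hardly turn. Without a Hipk1 array, where no test can be had, 26 list medians moved by at least 0.5 times their value, 11 by less and 1 turned sign. Named genes newly passed 20 times with the 4 arrays as labelled and 25 times in the value table. Lists lost their call 88 times, 33 of them with an estimated correlation and 33 with fry. The cause was not tested unless one is given.

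No gene was called in any comparison under any other background correction, filter, probe choice, variance model, weighting or threshold, or without either Hipk2 array (0 to 0 in each). Array weights and the Hipk1 arrays alone gave back the main fit for Hipk1, with the same 1936 genes at an unadjusted p under 0.05 in limma. These settings are no separate check. No count was made without a Hipk1 array. For Hipk2, 230 genes were called with the 4 arrays as labelled and 2088 in the value table. Less the column labelled Hipk1 replicate 1 the table gave 8139 genes for Hipk1, 9271 for Hipk2 and 6135 for the difference. Less Hipk1 replicate 2 it gave 669, 9271 and 2527, because the residual then comes from the table's 2 alike Hipk2 columns only. The replicate numbers share only a number between slides (r = -0.0418 between deviations). With the replicate number as a block the 4 arrays gave 0, 0 and 0 genes and 11, 14 and 8 lists.

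Camera with an estimated correlation and fry each called 0, 0 and 0 lists, fry with smallest adjusted p of 0.777, 0.973 and 0.786. With 1 residual degree of freedom these counts could hardly have come out otherwise and do not speak against the calls. In camera, immediate early genes for Hipk1 went from p = 0.00771 to 0.213 at an estimated correlation of only -0.0065. With the 4 arrays as labelled, the smallest adjusted p of fry was 0.348, 0.223 and 0.407. Median centring gave 6 lists for Hipk1 (0 towards Cy3, 6 towards Cy5), 12 for Hipk2 (3 and 9) and 12 for the difference (4 above 0, 8 below), and the value table gave 8 for Hipk2. Leaving out a Hipk2 array gave 13 to 14 lists for Hipk2 and 6 to 8 for the difference. CDK inhibitors lost the call without Hipk2 replicate 1 (adjusted p = 0.0544), and early progenitor (adjusted p = 0.0561) and mast cell genes without Hipk2 replicate 2. An intensity trend with a robust prior left 12 lists for Hipk2 and 6 for the difference. Interferon (adjusted p = 0.489) and G1 to S phase lost the call there. The correlation between targets was 0.67 under median centring.

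Median centring leaves a trend with intensity (Spearman's rho of -0.453, -0.804, -0.825 and -0.783 on the 4 arrays, against 0.0405, 0.0111, -0.0377 and 0.000196 after loess) and moves the median of all genes to between -0.131 and -0.119. Under it the Hipk1 medians were -0.23 for globin, -0.10 for heme, -0.064 for membrane, -0.17 for erythroid transcription factors, -0.018 for late maturation, -0.28 for G2 and mitosis, -0.35 for ER stress and -0.019 for immediate early genes. The Hipk2 medians were -0.61, -0.50, -0.47, -0.28, -0.14 and -0.53 for the first 6 of these and -0.11 for CDK inhibitors. Hipk1 was at -0.34 and Alad at -0.086 in the Hipk1 comparison, and Hipk3 at -0.26, Urod at -0.30, Mpp1 at -0.031 and C1qb at -0.10 in the Hipk2 comparison. Among intensity-matched lists under it, late maturation lay at percentiles 99.99 to 100 over the 4 arrays, globin at 14.4 to 98.4 and the other erythroid lists at 83.4 to 100.

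In the value table the Hipk2 comparison gave 0.020 for Hipk1, 0.26 for Isg15, 0.51 for Irf9, -0.0014 for G2 and mitosis and 0.15 for interferon genes. As means of their probes, Hipk3 was at 0.0017 and Hipk1 at 0.36 in the Hipk1 comparison, and Hipk2 at 0.68 in the Hipk2 comparison. With an array left out, Hipk1 in the Hipk1 comparison ranged from -0.26 to 0.42, Hipk3 there from -0.22 to 0.15, Hipk2 in the difference from -0.17 to 1.39, interferon in the difference from -0.0015 to 1.22, and Hipk2 in the Hipk2 comparison from 1.66 to 1.77, but it was 1.04 under median centring. Without a Hipk1 array no residual degrees of freedom remain, so these values have no test. A slide or scan block (it matches the target), Hipk2 alone (1 sample) and the difference alone were not run. Spots near background limit ratios of weak genes.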

Other observations

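All tests in this part were chosen only after the result was seen. A list of 32 genes known to rise in low oxygen or to encode glycolytic enzymes was written after the gene values were seen, and 31 of them were measured, 2 of which are also in lists fixed before. Their median was -0.55 and -0.83 on Hipk1 replicates 1 and 2 and -0.17 and -0.23 on Hipk2 replicates 1 and 2, with 24 of 31 genes higher in Cy5 on both Hipk1 arrays and 23 on both Hipk2 arrays. On Hipk1 replicates 1 and 2, lactate dehydrogenase (Ldha) was at -1.88 and -1.11, hexokinase (Hk2) at -1.81 and -1.33, the mitophagy receptor Bnip3 at -1.38 and -1.81, and the enzymes Pgam1 and Tpi1 at -1.59 and -1.18, and -0.93 and -1.30. The glucose transporters Slc2a1 (1.43 and 0.20) and Slc2a3 (0.51 and 0.32) and hexokinase Hk1 (0.74 and 0.04) lay on the other side. The median of Hipk2 minus Hipk1 was 0.499, with 22 genes higher on the Hipk2 arrays than on both Hipk1 arrays, and in the authors' value table the medians of the Hipk2 columns were 0.12 and 0.01. These genes were grouped on the same data, so their shared direction was not tested.

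Hipk2 was higher in Cy3, the channel labelled knockdown. Between the Hipk1 arrays the 7 Hipk1 and Hipk2 probes differed by a median absolute 0.688, 6 of them by over 0.2, where a dye bias alone would give like ratios. Yet 69 bright probes with 5 or more spots differed there by a median of 0.359, so passing 0.2 cannot decide this. The brightest Hipk2 probe gave 0.33 and 1.88 on these arrays, which a dye bias alone would not give. A_51_P318292 gave 0.58, 0.69, 0.64 and 0.60 on the 4 arrays, so a dye bias stays open for that probe. Dye labels turned round, with the control RNA in Cy3, may account for the higher Cy3 signal of Hipk2, which stays open. The spread between the Hipk1 arrays in Cy5 was 7.09 times that in Cy3, and one control RNA on both arrays would leave Cy3 alike. One knockdown RNA on both arrays, set against differing controls, would do the same, so this spread cannot decide the question. The array labelled Hipk1 replicate 2 may hold RNA with Hipk2 lowered, as its brightest Hipk2 probe differed by 0.169 from the Hipk2 mean, but that value raised the question, and probe A_52_P29583 of Hipk2 lay at -0.64 there against 0.27 and 0.24 on the Hipk2 arrays, so this stays open. That it holds the same RNA pair as the Hipk2 arrays is argued against by the 135 other genes at least 2-fold on both Hipk2 arrays, whose median in the Hipk2 direction was 0.327 on it and 0.832 on Hipk1 replicate 1. Probes outside the part of the transcript that an shRNA affects were not analysed here, and an effect of the knockdown on other transcripts of the locus stays open as untested.

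The Hipk2 columns of the authors' value table differ from the Hipk2 scanner files. Other processing of the same hybridisations is argued against by a highest correlation of 0.823 across genes, where the Hipk1 columns reached 0.963 and 0.991. The same RNA pair hybridised again is argued against by the interferon list, whose median was 0.896 higher in the columns (0.147) than in the files (-0.749), with 29 of 30 genes lower in the files. A table made from other Hipk2 samples could give such values and stays open, and no biological explanation was tested.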
